A study of Mus musculus with 5 samples.

How the data were processed

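The series holds 5 Visium sections of liver. The 4 mouse sections, 1 per group of diet and feeding state, were fresh frozen and 10 µm thick and read with Visium v1 chemistry, per the labels' protocols. Section 5, from a humanized chimeric mouse (uPA SCID background) that had been refed, was fixed with PFA and read with Visium v2 and CytAssist, per the labels' protocols. The series design gives a fast of 12 h and refeeding for 4 h; sections whose titles say fed were taken as refed for 4 h. The number of animals, their sex and the day of collection are not given in the sources used here. Groups have no replicates: each comparison sets single sections against each other, or pairs of sections across the other factor.

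The deposited matrices hold counts: whole UMI numbers per gene and per spot under tissue, with no normalization, per the file headers. They were made with Space Ranger 2.0.0 against builds mm10 and GRCh38, per the submitters' processing notes; for the humanized section the file header gives no software version. The mouse matrices list 32285 genes and the humanized matrix 18085, and per-gene sums of the matrices equal the count column of the deposited spatial enrichment tables. Those tables also hold a deposited score, the Moran statistic of each gene across the spots of a section. The other deposited files used here hold spot barcodes, gene names and spot positions, per the file headers, and image scale factors were not used here. For the plotted and listed values, counts were summed over the spots of each section and divided by the section total, then scaled to CPM, and log2 ratios were taken between sections. The intervals beside ratios and shares are 95% exact Clopper-Pearson intervals of the counts. A section with 0 UMIs was set to a floor of 3 counts and its ratio given as a bound.

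Feeding state and diet were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, 2-sided; TMM normalization; filterByExpr) on section sums with the additive model of diet and feeding state, which leaves 1 residual degree of freedom. The median prior degrees of freedom were 15.2 and the coefficient that edgeR names biological variation was 0.219. The residual degree of freedom is the diet by feeding interaction. Standard errors and p-values for feeding and diet rest on it and on a prior shared across genes. They do not measure the spread between animals of a group, and a gene whose feeding effect differs between diets gets a larger error. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05; calls adjusted over the list alone are given beside these. The difference between diets in the feeding effect leaves no residual degrees of freedom and is given as a value without a test. For zonation each spot received a score, the mean z-score of 9 portal markers minus that of 9 central markers (7 and 8 in the humanized section). The spots of each section were split into 4 equal groups by this score, of which the lowest is called the central zone and the highest the portal zone (502, 362, 429 and 541 spots per zone in refed chow, fasted chow, refed high-fat and fasted high-fat). Zone sums were tested in edgeR with section as a block (3 residual degrees of freedom) and zone by feeding and zone by diet terms (2 residual degrees of freedom), with a coefficient of variation of 0.0955. Score markers are left out of the counts of zonal calls and of list members. The zone by feeding and zone by diet terms each set 2 sections against 2. Their p-values rest on these sections and a prior shared across genes, and do not measure the spread between animals of a group. Spots were never used as replicates. Between 182 and 274 mouse spots per section lay within 0.1 standard deviations of a zone boundary.

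For the dual-pathway shares, spots of at least 3000 UMIs were thinned to 3000 UMIs by random sampling. The UMIs of the core genes of gluconeogenesis (Pck1, G6pc, Fbp1 and Pcx) and of lipogenesis (Fasn, Acaca, Acly, Scd1, Elovl6 and Me1) were summed, and a spot counted as high in both when each sum was above its median over the pooled mouse spots, sections weighted equally. The ratio of observed to expected spots uses each section's own medians. Gene lists were fixed for 16 pathways and 13 sets of markers: gluconeogenesis and lipogenesis with their core lists, insulin and glucose handling, cholesterol synthesis, fatty acid oxidation and ketogenesis, lipid droplets and uptake, amino acid catabolism and urea, bile acids, acute phase, endoplasmic reticulum chaperones, clock, interferon, stress and immediate early genes and fibrosis; markers of Kupffer cells, recruited macrophages, endothelial, stellate, cholangiocyte, B and plasma, T and NK, neutrophil, erythroid, smooth muscle and mesothelial cells, and the 2 score lists. List medians cover members with at least 5 CPM and are set against 10000 random lists drawn from 20 bins of matched expression; a percentile of 0 or 100 means that none of the random lists was as extreme. Random lists are drawn gene by gene, while members of a list can move together from one animal to another. A percentile thus holds no spread between animals and is not a test of feeding or diet. Counting intervals of medians come from 1000 Poisson draws.

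Design, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names all core genes; the 10 highest and 10 lowest genes for feeding and for diet by the smaller of the 2 within-group ratios, of the same sign and with at least 20 CPM in 1 section; up to 4 members per list by the same measure; the 10 genes farthest to each side in zonation with the same sign in 4 sections, score markers left out; and the 5 genes with the largest opposite feeding ratios of at least 2-fold at 50 CPM or more. It gave 137 genes. List members named because they passed a test, and genes named for a zone by diet call, were chosen after their values were seen. Model genes, ribosomal and mitochondrial genes were not named. The floor of 3 counts equals 0.103, 0.264, 0.0944 and 0.0656 CPM in refed chow, fasted chow, refed high-fat and fasted high-fat.

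The fits were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. Each gene was drawn around its pooled mean with 1 common dispersion, without an effect of another factor, an interaction or a section difference other than depth. The recovery and the false calls belong to that setting and need not hold for these data. For feeding (12979 genes) 27% of the 2-fold and 93% of the 4-fold changes were recovered, for diet (12959 genes) 24% and 89%, for zonation (11478 genes) 89% and 99%, and for zone by diet (11484 genes) 43% and 90%; 4, 1, 6 and 3 unchanged genes were called. Alternatives were RLE normalization, DESeq2 1.42.0, no low-count filter, spots of at least 3000 UMIs, abundant genes left out of the library size, thinning of all sections to the smallest, each spot weighted equally, other zone widths (3 or 2 equal groups), a score from 6 markers, no section block, leaving out each section in turn, and for the shares other thresholds, thinning to 1500 UMIs, no thinning, no Scd1 and equal gene weights. In the fits that leave out a section the other factor is not modelled, and a lone section is assumed to vary like the others. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.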

Results

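Gene expression in liver was measured by spatial transcriptomics on the Visium platform, in which barcoded spots on a slide capture RNA from the tissue above them. Each captured molecule is counted once as a unique molecular identifier (UMI). The 4 mouse sections came from C57BL/6J mice and formed a 2 by 2 layout of diet (chow, or a diet with 60% fat given for 3 months from 6 weeks of age) and feeding state (fasted for 12 h, or refed for 4 h), with 1 section per group. Section 5 came from a refed chimeric mouse whose liver was repopulated with human hepatocytes (humanized liver) and was read with human probes. The sections held 2006 spots with 29185237 UMIs (refed chow) and 1446 spots with 11367530 (fasted chow). There were 1715 spots with 31771577 (refed high-fat), 2163 spots with 45719328 (fasted high-fat) and 2972 spots with 91002968 (humanized). The median spot held 13992 UMIs in refed chow, 6364.5 in fasted chow, 18383 in refed high-fat, 20992 in fasted high-fat and 29372 in the humanized section. The fasted chow section stood apart in depth, with 475 spots under 3000 UMIs against 15, 14 and 8 in the other mouse sections. It had the highest mitochondrial share, 5.60% against 3.79%, 4.64% and 4.18%.

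Fasted and refed livers differed in genes of fat oxidation, the acute phase response, protein folding and the clock. The fasted sections were registered apart from the refed ones, and no label gives the hour of collection. A difference in handling or hour cannot be told apart from feeding in any fasted against refed comparison given here. Of 18 tested genes of fatty acid oxidation and ketogenesis, 6 rose with fasting (7 adjusted over the list alone) and none fell. Among them was Cpt1a, an enzyme that links long-chain fatty acids to carnitine for entry into mitochondria. It rose by log2 1.41 ± 0.25 (SE, edgeR adjusted p = 0.00505), with ratios of 1.44 in chow and 1.53 in high-fat diet. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 2.39 ± 0.26 (adjusted p = 9.28e-05), and Vnn1 by 1.55 ± 0.24 (adjusted p = 0.00218). Cyp4a14, an omega-hydroxylase from a family of near-identical genes, had ratios of 3.85 in chow and 1.25 in high-fat diet. The median fasted over refed ratio of the list was 0.67 in chow and 0.67 in high-fat diet, percentiles 99.99 and 100 of 10000 random lists of matched expression. Such percentiles describe single sections, hold no spread between animals and are not a test of feeding or diet. Many of these genes are central in the lobule, and the central marker list also had medians of 0.58 in chow (percentile 99.95) and 0.26 in high-fat diet (percentile 92.99). Of the 6 risen genes Acot1, Cyp4a10, Cyp4a14 and Vnn1 were themselves called central, so unequal sampling of the lobule stays open for them. Cpt1a and Angptl4 were not called zonal over all genes. Their portal over central differences (0.05 and -0.38) were smaller than their rises with fasting.

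Acute phase genes were lower in fasted than in refed liver: 7 of 14 fell (10 passed when adjusted over the list alone, 9 lower and 1 higher). Saa2 and Saa1, serum amyloid paralogs whose reads are hard to tell apart, fell by 4.97 and 4.34 on the log2 scale (adjusted p = 5.14e-07 and 9.92e-06). Lcn2, an iron-siderophore binding protein, had ratios of -2.47 in chow and -4.26 in high-fat diet. Hamp, the iron hormone hepcidin, fell too, with ratios of -1.35 in chow and -1.11 in high-fat diet. The median of the list was -0.80 in chow and -1.24 in high-fat diet. Of the 14 genes 9 were portal in the lobule. The portal marker list had medians of 0.12 in chow (percentile 80.2) and -0.46 in high-fat diet (percentile 0.26). Stress genes and chaperones of the endoplasmic reticulum, a list called chaperones elsewhere in the text, were also lower, 8 of 12 falling (9 adjusted over the list alone). Hspa5, the main chaperone of that compartment, fell by 1.72 on the log2 scale (SE 0.30; adjusted p = 0.00434). Sdf2l1, Creld2, Hyou1 and Manf fell with it, Sdf2l1 with ratios of -2.88 in chow and -2.29 in high-fat diet. The medians of the list were -0.99 in chow and -1.30 in high-fat diet. It also holds the transcription factors Ddit3, Atf4 and Xbp1, of which Ddit3 was among the 8 and Atf4 passed over the list alone.

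Clock genes differed in both directions: 3 of 12 rose and 3 fell with fasting (9 passed when adjusted over the list alone, 6 higher and 3 lower). Nr1d1, Nr1d2 and Dbp were higher in fasted liver, Nr1d1 with ratios of 3.27 in chow and 2.64 in high-fat diet. Arntl fell by 2.65, Cry1 by 1.38 and Per2 by 1.22 on the log2 scale. Among the genes with the largest ratios shared by both diets were Gpcpd1, a glycerophosphodiesterase (3.19 ± 0.26, adjusted p = 7.03e-06), and Rgs16, a regulator of G protein signalling (ratios 3.31 in chow and 7.80 in high-fat diet). On the same side were Depp1 (4.12 in chow and 2.52 in high-fat diet), Acot3, Socs2 and Mt2. On the lower side were Angptl8 (ratios -3.82 in chow and -2.08 in high-fat diet), Slc30a10, Tubb2a and Ppp1r3c, a glycogen-targeting phosphatase subunit (-2.84 in chow and -2.18 in high-fat diet). In the list of insulin and glucose handling 3 of 15 genes passed (7 adjusted over the list alone, 4 higher and 3 lower): Ppp1r3c fell. Igfbp1, an insulin-like growth factor binding protein, rose by 2.98 ± 0.50 (adjusted p = 0.00381), as did Ppp1r3g, which rested on 2 and 4 UMIs in the refed sections (ratio 7.21, interval 5.32 to 10.27 in chow). Cyp2b9 also passed (fitted 2.89), with a ratio of 3.13 in high-fat diet. In chow it had 1 and 0 UMIs, so no ratio is given, and without the fasted high-fat section its fitted value was -8.90, in a fit that does not model diet.

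In bile acid synthesis Cyp7a1, the rate-limiting enzyme, fell by 1.20 on the log2 scale (adjusted p = 0.0125) and Cyp8b1, the sterol 12-alpha-hydroxylase, rose by 1.02 (adjusted p = 0.0455). These were the 2 of 9 list genes that passed (3 adjusted over the list alone, with Nr0b2, which was higher). Of 13 lipid droplet and uptake genes Plin4 and Cidec rose (4 adjusted over the list alone, with Plin2 and Mogat1), and without the fasted high-fat section the fitted value of Cidec was -0.50, in a fit that does not model diet. Its ratio was 2.06 in high-fat diet and 0.51 in chow, or -0.01 in chow with each spot weighted equally. None of the 14 tested genes of amino acid catabolism and urea synthesis, nor of the 9 interferon genes, passed over all genes or over the list alone. Over all genes, 270 of 12981 passed at an adjusted p under 0.05 in an edgeR fit of diet plus feeding state, 118 higher and 152 lower in fasted liver, and 1471 had an unadjusted p under 0.05. The comparison sets 2 fasted against 2 refed sections with 1 residual degree of freedom, the diet by feeding interaction, and holds no spread between animals of a group. No gene passed in edgeR when the fasted chow or the fasted high-fat section was left out (1729 and 1848 at an unadjusted p under 0.05), against 45 without refed chow and 40 without refed high-fat. Thinning all sections to the UMI total of fasted chow left 20 of the 270 genes, normalization by RLE left 158, and testing without a low-count filter gave 538. DESeq2 called 226.

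The title of the series speaks of spots with both of 2 pathways without naming them, and gluconeogenesis and lipogenesis were chosen here. Within chow, the fasted section had more Pck1, an enzyme early in gluconeogenesis, and less Fasn, Acly, Acaca and Elovl6 of lipogenesis than the refed section. Pck1 (ENSMUSG00000027513, chromosome 2 from 173153073 to 173159274) stood at 1931 CPM (UMIs scaled to the section total) fasted against 543 refed, a log2 ratio of 1.83, interval 1.80 to 1.86. G6pc (ENSMUSG00000078650, chromosome 11 from 101367716 to 101377903), the glucose-6-phosphatase, stood at 186 against 96.3 (0.95, interval 0.87 to 1.03). Fasn (ENSMUSG00000025153, chromosome 11 from 120805958 to 120825166), the fatty acid synthase, stood at 77.2 CPM fasted against 777 refed, a log2 ratio of -3.33, interval -3.43 to -3.23; Acly was at -1.61, Acaca at -1.46 and Elovl6 at -1.18. Scd1, the stearoyl-CoA desaturase and by far the most abundant of the core genes, was nearly equal, 5289.7 against 5411 CPM (-0.03, interval -0.05 to -0.02). Fbp1 (-0.03) and Pcx (0.05) also lay close to 0, both with the opposite sign when each spot was weighted equally, and Me1 was at 0.14. Of 13 measured lipogenesis genes 7 were at least 1.5-fold lower and 1 at least 1.5-fold higher in fasted chow liver; their median of -0.61 (interval -0.85 to -0.41) had percentile 0. Of 18 cholesterol synthesis genes 14 were at least 1.5-fold lower and none higher, with a median of -1.05 (percentile 0).

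Within high-fat diet Pck1, G6pc, Fasn, Acly and Elovl6 differed less than in chow, Acaca in the other direction, and Me1, Scd1 and Pcx more. Pck1 stood at 1029 CPM fasted against 705 refed (0.55, interval 0.52 to 0.57), G6pc was at 0.13, interval 0.09 to 0.18, and Fbp1 and Pcx at -0.09 and 0.40. Fasn had 283 CPM fasted against 318 refed (-0.17, interval -0.20 to -0.13), and Acly, Acaca and Scd1 were at -0.31, 0.21 and -0.29. Elovl6 was at -0.03, with the opposite sign when each spot was weighted equally, and Me1, malic enzyme, at 1.64, interval 1.58 to 1.71. The lipogenesis median was 0.21 (interval 0.10 to 0.33; percentile 82.8), with 6 genes at least 1.5-fold higher and none lower. The cholesterol synthesis median was 0.48 (percentile 99.99), with 8 genes higher and 3 lower. For the whole gluconeogenesis list the medians were 0.05 in chow (percentile 65.6) and 0.28 in high-fat diet (percentile 93.5). In the fit over both diets none of the 10 core genes passed over all genes: Pck1 was at 1.11 ± 0.32 (adjusted p = 0.0957), Fasn at -1.82 ± 0.52 (adjusted p = 0.0892) and Acly at -1.03 ± 0.29 (adjusted p = 0.0889). Adjusted over the list alone, Pck1 passed among the 4 gluconeogenic core genes, and Fasn, Acly, Elovl6 (lower) and Me1 (higher) among the 6 lipogenic ones. Over the longer lists 0 of 10 gluconeogenic genes passed (1 adjusted over the list alone), and 1 of 13 lipogenic genes (Elovl5, higher, adjusted p = 0.0287; 5 adjusted over the list alone, 2 higher and 3 lower). Of 18 cholesterol genes 2 passed, Insig1 and Mvd, both lower (4 adjusted over the list alone). The difference between diets in a feeding ratio has no test with 1 section per group, and the intervals cover counting error only.

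**Figure D1:**
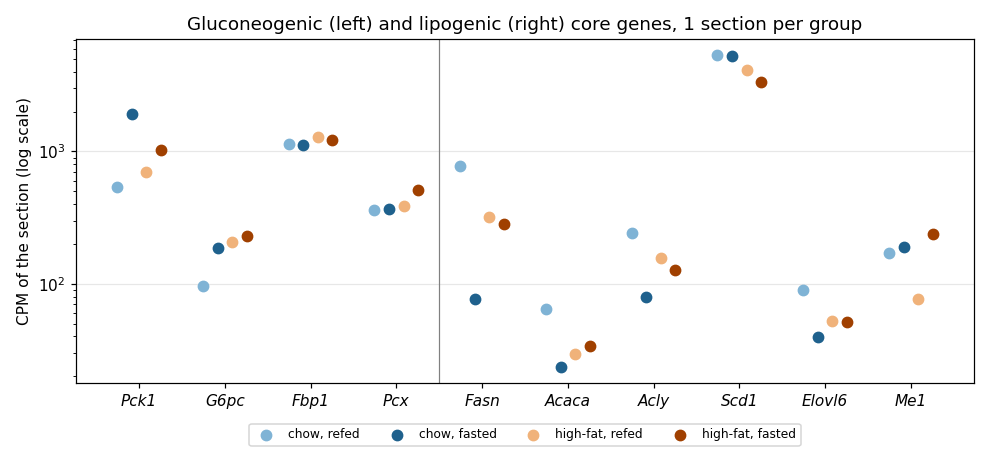
CPM (log axis) of the 10 core genes in each of the 4 mouse sections, 1 point per section. Fasn stands at 777 in refed chow and 77.2 in fasted chow, against 318 and 283 in high-fat diet.

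Feeding ratios in the 2 diets were related across genes, with Pearson r = 0.390 and Spearman rho = 0.259 over 4738 genes, which are not independent replicates. At least 2-fold ratios of the same sign in both diets were seen for 107 genes and of opposite sign for 15. By the rule for opposite ratios, 9 of 2331 genes with at least 50 CPM qualified. The 5 with the largest ratios were Tcim (-2.23 in chow and 1.73 in high-fat diet), Mup9 of the near-identical major urinary proteins (1.71 in chow and -1.74 in high-fat diet), Serpina12 (-1.59 in chow and 1.60 in high-fat diet), the water channel Aqp8 (-3.16 in chow and 1.55 in high-fat diet) and Pklr, the liver pyruvate kinase (-1.34 in chow and 1.72 in high-fat diet). The insulin and glucose handling list had medians of -0.33 in chow and 0.52 in high-fat diet. Scaling by TMM in place of the section total moved the median of all genes from 0.09 to -0.04 in the feeding ratio of high-fat diet and from -0.10 to -0.01 in the diet ratio of refed liver, and the ratios of those comparisons stand relative to these shifts.

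**Figure D2:**
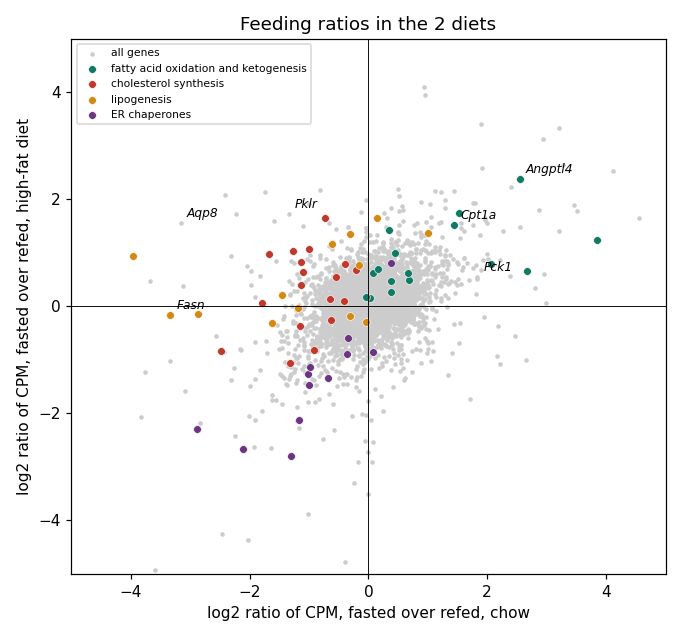
Log2 ratio of CPM, fasted over refed, in chow (horizontal axis) against high-fat diet (vertical axis), 1 point per gene for 4738 genes, with 4 gene lists in colour and 2 genes lying beyond the axes. Cpt1a (1.44 and 1.53) lies on the same side in both diets, while Fasn (-3.33 and -0.17) is far below 0 in chow and close to 0 in high-fat diet.

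High-fat diet liver had more transcript of genes of lipid droplets and lipid uptake than chow liver in both feeding states. Of 13 such genes 6 rose and none fell (10 adjusted over the list alone), with medians of 1.09 refed and 1.11 fasted, both at percentile 100. Apoa4, an apolipoprotein, rose by log2 3.52 ± 0.39 (SE; adjusted p = 0.00011), and Cidec, a droplet fusion protein, by 2.28 ± 0.32 (adjusted p = 0.00143). Also higher was Cd36, a fatty acid uptake protein (1.15 ± 0.24, adjusted p = 0.0287; ratios 1.09 refed and 1.14 fasted). G0s2 and Plin4 rose as well. The collagen genes Col3a1 (1.92 ± 0.28, adjusted p = 0.00157) and Col1a1 (1.44 ± 0.32, adjusted p = 0.0372) were the 2 of 9 fibrosis genes that passed (5 adjusted over the list alone, 4 higher and 1 lower). Stellate cell markers had medians of 0.66 refed and 0.74 fasted (percentiles 99.99 and 99.87). Members ranged from -0.45 to 1.08 refed and from -0.56 to 1.28 fasted, and 0 of 8 passed over all genes (3 adjusted over the list alone). The collagen values thus do not tell more stellate cells from more transcript per cell. Of 7 recruited macrophage markers Gpnmb (5.09 ± 0.96) and Mmp12 (3.85 ± 0.60) rose (3 adjusted over the list alone, with Trem2). All 3 lie under 5 CPM in every section, and the 2 markers with at least 5 CPM had medians of -0.03 refed and -0.15 fasted. In the acute phase list Lcn2 (3.64 ± 0.39) and Saa2 (1.48 ± 0.28) rose (2 of 14; 3 adjusted over the list alone, with Saa1), and without the refed high-fat section the fitted values of Saa2 and Saa1 were -2.55 and -2.35. That fit does not model feeding state, which moved both genes, and their high-fat over chow ratios were positive in both states (Saa2 1.72 refed and 1.16 fasted, Saa1 1.73 refed and 0.40 fasted).

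The largest rise among the genes named for diet was that of Cyp2b9, a cytochrome P450: 150 UMIs in refed high-fat liver against 1 in refed chow, a log2 ratio of 7.11, interval 4.61 to 12.42. There were 1889 against 0 UMIs in the fasted sections, at least 157-fold higher when the floor of 3 counts is taken for fasted chow. Cfd, complement factor D, rose by 4.91 ± 0.37 (adjusted p = 2.24e-06; ratios 4.09 refed and 5.88 fasted), and Hamp2, Adgrv1, Cyp17a1, Ppp1r3c, Slc17a4 and Anxa2 rose in both feeding states. Moxd1 fell, with a ratio of -5.31 refed and -9.70, interval -15.01 to -7.21 fasted, the latter from 1 UMI in fasted high-fat liver. Csad, of taurine synthesis, fell by 2.30 on the log2 scale (ratios -2.31 refed and -2.35 fasted). Cyp7b1, the oxysterol hydroxylase and the single gene of 9 in the bile acid list to pass (2 adjusted over the list alone, with Nr0b2, which was higher), fell by 1.79 (adjusted p = 0.00214). Cyp3a11, Ugt2b38, Mup7, Mup12 and Cyp4a31, all members of families of near-identical genes, and Pfkfb3 also fell. The heat shock genes Hspa1b and Hspa1a fell, Hspa1b with ratios of -1.92 refed and -3.81 fasted (2 of 11 stress and immediate early genes; 3 adjusted over the list alone, with Gadd45b). Nr1d1 (1 of 12 clock genes; 4 adjusted over the list alone, 3 lower and 1 higher), Angptl4 (1 of 18 fat oxidation genes) and Hyou1 (1 of 12 chaperones; 4 adjusted over the list alone) fell in high-fat liver. Without the fasted chow section the fitted values of Nr1d1 and Angptl4 were 0.67 and 0.39, again without feeding state in the fit. Their high-fat over chow ratios were negative in both states (Nr1d1 -1.17 refed and -1.80 fasted, Angptl4 -1.22 refed and -1.40 fasted).

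Between diets the lipogenic genes differed in opposite directions in the 2 feeding states. In refed liver the lipogenesis median was -0.79 (high-fat over chow; interval -0.84 to -0.69, percentile 0), with 10 of 13 genes at least 1.5-fold lower, and Fasn was at -1.29, interval -1.32 to -1.26. In fasted liver the median was 0.69 (interval 0.59 to 0.79, percentile 100), with 7 genes higher and 1 lower, and Fasn was at 1.88, interval 1.78 to 1.98. Acaca, Acly, Elovl6 and Me1 had the same signs as Fasn, from -1.16 to -0.62 in refed and from 0.34 to 0.69 in fasted liver, and Scd1 was lower in both, at -0.40 and -0.66. The cholesterol synthesis medians were -0.93 refed and 0.26 fasted. Pck1 was at 0.38 refed and -0.91 fasted, G6pc at 1.11 and 0.29, Fbp1 at 0.19 and 0.12, and Pcx at 0.10 and 0.45. The gluconeogenesis medians were 0.10 refed and 0.29 fasted. No gene of the 10 gluconeogenic or the 13 lipogenic genes passed the diet test, over all genes or over the list alone. In edgeR 0 of 18 cholesterol genes passed over all genes (3 adjusted over the list alone, Sqle, Cyp51 and Insig1, all lower). Over all genes, 131 of 12981 passed for diet in edgeR, 74 higher and 57 lower in high-fat liver, and 1291 had an unadjusted p under 0.05. No gene passed without refed chow, without fasted chow or without refed high-fat (1064, 497 and 863 at an unadjusted p under 0.05), and 18 without fasted high-fat. Of the 131 genes, 12 remained after thinning to the smallest section total, 64 with RLE, 72 with abundant genes left out of the library size and 80 in spots of at least 3000 UMIs, and 354 passed without a low-count filter. DESeq2 called 110.

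Zonation, the difference between liver tissue near the central vein and near the portal tract, gave the most calls of the comparisons made here. Spots were ordered in each section by a score of known central and portal marker genes, and the lowest and highest of 4 equal groups are called the central and portal zones. On the central side, apart from the score markers, were Slc13a3, a dicarboxylate transporter (log2 portal over central -3.81 ± 0.13, 14.0-fold; adjusted p = 1.68e-11), Cyp2a5, Cib2, Lhpp, Rdh9, Cidea and, from families of near-identical genes, Cyp2c40 (-3.91 ± 0.27), Cyp2c37, Cyp2c38 and Serpina7. On the portal side were Spp1, osteopontin (11.3-fold; adjusted p = 4.46e-10), Sds, the serine dehydratase (2.84 ± 0.14, 7.17-fold), Aldh1b1, Mmd2, Cdh1, which encodes E-cadherin, Tff3, Hsd17b6, Ctnnbip1, Cryl1 and Slc3a1. In total 2159 of 11591 genes passed in edgeR, 987 portal and 1172 central, of which 1976 had 1 sign in all 4 sections. Without section as a block 176 passed, and DESeq2 called 1179.

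Gluconeogenic genes lay mostly on the portal side and lipogenic genes were split. Of 10 gluconeogenesis genes 6 were portal and 1 central (8 passed when adjusted over the list alone, 7 portal and 1 central): Pck1 at 1.13 ± 0.15 (adjusted p = 4.75e-05), Fbp1 at 0.89 ± 0.09 (adjusted p = 6.62e-06) and G6pc at 0.69 ± 0.12 (adjusted p = 0.000647) were portal, G6pc with ratios of 0.95 in refed chow, 0.95 in fasted chow, 0.68 in refed high-fat and 0.08, near even, in fasted high-fat. Pcx, pyruvate carboxylase, was central at -0.28 ± 0.09 (adjusted p = 0.0442). Of 13 lipogenesis genes 1 was portal and 3 central (5 adjusted over the list alone, 1 portal and 4 central). Acly, ATP citrate lyase, was portal at 1.16 ± 0.11 (adjusted p = 2.56e-06). Me1 (-0.68 ± 0.11, adjusted p = 0.000316), Acss2 (-0.25) and Slc25a1 (-0.30) were central. Fasn (-0.06 ± 0.18, adjusted p = 0.866), Acaca (0.26), Scd1 (-0.22) and Elovl6 (-0.23) did not pass. Fasn was at 0.09 without section as a block, at 0.14 without refed high-fat and at 0.16 without fasted high-fat, and Elovl6 at 0.02 without fasted high-fat. Fat oxidation genes were central (9 of 18, none portal; 10 adjusted over the list alone), as were lipid droplet genes (9 central and 1 portal of 13; 10 adjusted over the list alone). Acute phase genes (9 of 14; 11 adjusted over the list alone), all 9 Kupffer cell markers and all 5 tested cholangiocyte markers were portal, the marker lists likewise adjusted over the list alone. Of the 14 genes of amino acid catabolism and urea synthesis 3 are score markers (Gls2, Hal and Oat), and the other 11 all passed, 9 portal and 2 central (11 adjusted over the list alone). Of 18 cholesterol genes 1 was portal and 4 central (7 adjusted over the list alone, 2 portal and 5 central). In the fasted chow section the markers of the 2 sides were barely opposed across spots (mean correlation -0.06 against -0.41, -0.46 and -0.51). Its portal zone was shallower than its central zone, a median of 5801.5 against 10460.0 UMIs.

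**Figure D3:**
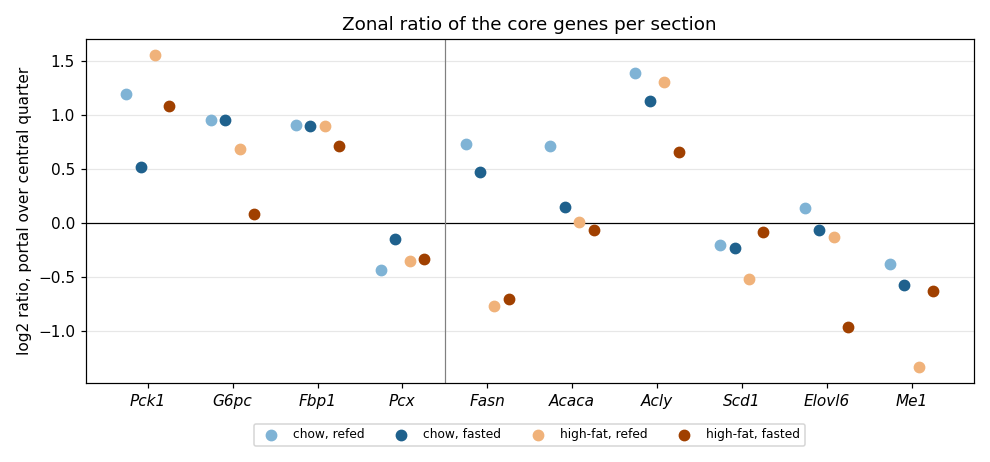
Log2 ratio of counts in the portal over the central zone for the 10 core genes in each of the 4 mouse sections, 1 point per section. Fasn lies above 0 in both chow sections (0.73 and 0.47) and below 0 in both high-fat sections (-0.76 and -0.71), while Fbp1 lies between 0.71 and 0.91 in all 4.

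The zonal ratio differed between diets for 30 genes, 20 shifted toward the portal side and 10 toward the central side in high-fat liver (edgeR, zone by diet term). At an unadjusted p under 0.05 there were 1105 genes. The term sets 2 sections against 2 and holds no spread between animals of a group. Fasn was portal in chow (0.73 refed and 0.47 fasted) and central in high-fat liver (-0.76 and -0.71), a difference of -1.20 ± 0.15 (adjusted p = 0.00182). Thrsp, a protein of lipogenic liver, shifted the same way (-1.30 ± 0.19, adjusted p = 0.00507). These were 2 of 13 lipogenesis genes (4 adjusted over the list alone, all toward the central side). Of 18 cholesterol genes Idi1 (-1.22 ± 0.15, adjusted p = 0.00182) and Nsdhl (-1.03 ± 0.20, adjusted p = 0.0399) shifted centrally (10 adjusted over the list alone, all 10 centrally). Toward the portal side shifted Cd36 (1.64 ± 0.15, adjusted p = 9.63e-05; 1 of 13 lipid droplet genes, 4 adjusted over the list alone, 2 toward each side) and Hamp (1.52 ± 0.22, adjusted p = 0.00564; 1 of 14 acute phase genes, 5 adjusted over the list alone). So did the Kupffer cell gene Marco (1.47 ± 0.24, adjusted p = 0.0163; 1 of 9, 3 adjusted over the list alone) and Got1 (0.76 ± 0.14; 1 of 10 gluconeogenesis genes). With the 3 score markers left out, no amino acid gene passed over all genes, and 4 of 11 did when adjusted over the list alone, toward the portal side. Of those markers Gls2 shifted toward the portal side (0.84 ± 0.15, adjusted p = 0.0293), and Hal and Oat did not pass. Between feeding states no gene passed over all genes in edgeR (419 at an unadjusted p under 0.05; 1 gene with DESeq2). Of fat oxidation genes 6 of 18 passed when adjusted over the list alone, all shifted toward the portal side in fasted liver, among them Angptl4 (0.64) and Vnn1 (0.92), as did 3 of 13 lipid droplet genes. Of 5 erythroid markers, of another cell type, the 4 hemoglobin genes passed over the list alone and shifted the same way (median of the 5 markers 1.19). Alas2 did not pass. Among the 6 fat oxidation genes, Acot1, Cyp4a10, Cyp4a14, Angptl4 and Vnn1 were central when adjusted over the list alone. So were the hemoglobin genes Hba-a1, Hba-a2 and Hbb-bs. For these genes a shift toward the portal side can also be a weaker central excess. Zone markers were barely opposed in fasted chow (mean correlation -0.06 against -0.41, -0.46 and -0.51). A poorer split of zones in that section thus cannot be told apart from a feeding shift. The zone by diet count was 76, 128, 110 and 164 genes when refed chow, fasted chow, refed high-fat or fasted high-fat was left out. It was 174 without a low-count filter, 16 with DESeq2 and 18 with zones drawn from spots of at least 3000 UMIs (8 toward the portal and 10 toward the central side), all 18 among the 30. The zone by feeding count was 7, 15, 19 and 9 with the same sections left out in turn, 19 without a low-count filter and 4 with zones drawn from the deeper spots.

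Spots high in both pathways were most frequent in fasted chow liver. After each spot was thinned to 3000 UMIs and compared with the medians of the pooled mouse spots, both the gluconeogenic and the lipogenic core score were high in 40.4% of fasted chow spots (of 971 spots; 95% exact Clopper-Pearson interval 37.3 to 43.5) and in 14.9% of refed chow spots (296 of 1991; 13.3 to 16.5). The share was 9.99% in refed high-fat (170 of 1701; 8.61 to 11.5) and 9.84% in fasted high-fat (212 of 2155; 8.61 to 11.2). The gluconeogenic score was high in 69.7% of fasted chow spots against 20.5% of refed chow spots, and in 50.2% against 37.9% in high-fat diet. The lipogenic score was high in 60.1% of fasted chow, 77.3% of refed chow, 22.5% of fasted high-fat and 32.6% of refed high-fat spots. From these separate shares 41.9% of fasted chow spots would be high in both if the scores were independent, so the 40.4% is no excess of spots with both. Scd1 supplied most UMIs of the lipogenic score. Without it the fasted chow share was 8.44% and the highest share was that of fasted high-fat liver, 18.7%, with 15.9% in refed chow and 10.3% in refed high-fat. With genes weighted equally the shares were 20.5% in refed chow, 22.2% in fasted chow, 19.9% in refed high-fat and 29.7% in fasted high-fat. By zone, the share in refed chow ran from 5.22% in the central to 25.1% in the portal zone, and in fasted chow from 28.8% in the central zone through 48.1% and 50.4% to 34.2% in the portal zone. From the central to the portal zone it was 5.16%, 13.4%, 12.5% and 8.94% in refed high-fat, and 6.12%, 12.99%, 11.3% and 8.91% in fasted high-fat, highest in the middle groups.

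Within each section the scores of the 2 pathways were close to independent or slightly opposed. Against each section's own medians, the spots high in both were 0.972 of the number expected from independent scores in refed chow, 0.864 in fasted chow, 0.883 in refed high-fat, 0.904 in fasted high-fat and 0.982 in the humanized section. Spearman rho across spots, which are not replicates, was -0.04, -0.15, -0.13, -0.07 and -0.02 in that order. With the expectation taken within the 4 zone groups the ratios were 1.0, 0.919, 0.982, 0.941 and 0.998. Without Scd1 the ratios were 1.13 in refed chow, 0.983 in fasted chow, 1.0 in refed high-fat and 0.968 in fasted high-fat. These shares belong to single sections, so no test between groups is given.

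**Figure D4:**
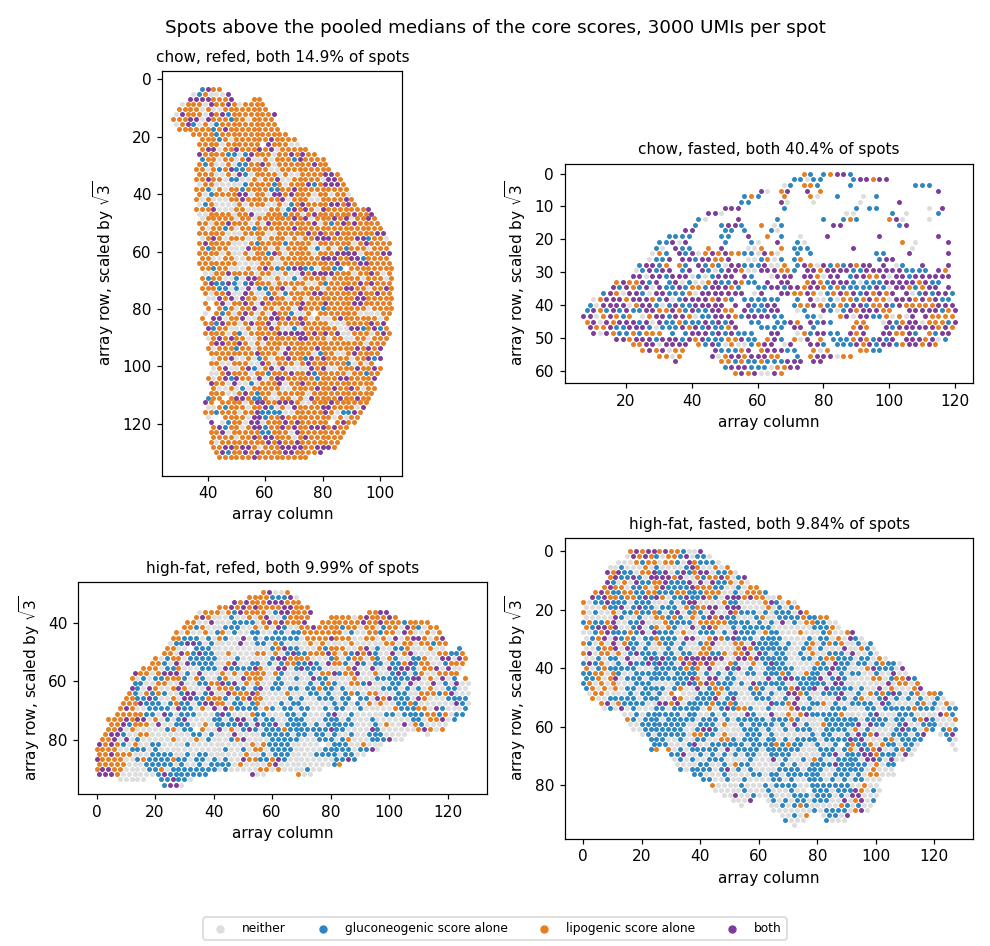
Position on the array (column and scaled row) of each spot of at least 3000 UMIs in the 4 mouse sections, coloured by which core score lay above the pooled median after thinning to 3000 UMIs. Spots high in both make up 40.4% in fasted chow and 14.9%, 9.99% and 9.84% in refed chow, refed high-fat and fasted high-fat.

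In the humanized refed section, the gluconeogenic core genes FBP1, G6PC, PCK1 and PC stood at 2064, 266, 105 and 89.3 CPM. Each gene is read by its own probes, so levels are not ranked between genes. Among lipogenic genes SCD stood at 670.0 and FASN at 612, with ELOVL6 at 88.2, ACACA at 29.3, ACLY at 25.3 and ME1 at 11.8. By the score of human zonal markers, G6PC (1.39, interval 1.33 to 1.45), PCK1 (1.36, interval 1.26 to 1.45) and FBP1 (1.16, interval 1.14 to 1.18) had more counts in the portal than in the central zone, as did ME1 (1.65, interval 1.36 to 1.95) and ACLY (0.86, interval 0.68 to 1.04). FASN was near even at 0.06, interval 0.02 to 0.09, PC was at 0.20, interval 0.11 to 0.29, SCD at -0.24, interval -0.27 to -0.21, ACACA at -0.30, interval -0.46 to -0.14 and ELOVL6 at -0.06, interval -0.15 to 0.03. Of 969 genes with the same symbol that were zonal in mouse liver, 606 (62.5%) lay on the same side here, with Spearman rho = 0.289 across genes, which are not independent. In this section the zonal score rose with depth across spots (Spearman rho = 0.41), and the portal zone held a median of 39544.0 UMIs per spot against 25251.0 in the central zone. The section was read with another chemistry and organism and was not compared in level with the mouse sections.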

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

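In this part 2 tests were stated before their results were seen, the cholesterol list within each zone and the zonal ratio of Fasn with zones from deeper spots; the tests on the share of spots under 3000 UMIs, on clock genes, without the fasted chow section, without Scd1, with thinning to 1500 UMIs and on turned zone labels were chosen after the result was seen. The zone by diet term gave 30 genes whose zonal ratio differed between diets in a test of the difference: among them Cd36 (1.64), Idi1 (-1.22), Fasn (-1.20), Thrsp (-1.30), Hamp (1.52), Marco (1.47), Got1 (0.76) and Nsdhl (-1.03). That test holds no spread between animals of a group. The feeding ratio had opposite signs in chow and high-fat diet, a difference that was not tested, for 9 genes, of which Tcim (-2.23 and 1.73), Mup9 (1.71 and -1.74), Serpina12 (-1.59 and 1.60), Aqp8 (-3.16 and 1.55) and Pklr (-1.34 and 1.72) had the largest ratios. The same holds, also untested, for the list medians of lipogenesis (-0.61 and 0.21), insulin and glucose handling (-0.33 and 0.52), cholesterol synthesis (-1.05 and 0.48) and stress genes (0.33 and -0.42). The lipogenesis median in high-fat diet was at percentile 82.8 and was 0.07 with TMM. That of the lipogenic core genes was negative in both diets (-1.32 and -0.10).

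The list medians of lipogenesis and cholesterol synthesis were below 0 for fasted over refed chow liver and above 0 in high-fat liver. The lipogenic core genes had medians of -1.32 in chow and -0.10 (interval -0.14 to -0.05) in high-fat diet, a smaller fall rather than none. Spots under 3000 UMIs held 4.94% of the UMIs of the fasted chow section, and a gene absent from all of them would have its summed log2 ratio moved by -0.0731, against a cholesterol median of -1.05, which argues against the spots under 3000 UMIs as the source. With each spot weighted equally the lipogenesis median in chow was -0.35, and the state of the tissue as a whole was not tested. Within zones the high-fat minus chow difference was 1.78 in the central and 1.26 in the portal zone for the cholesterol list. For lipogenesis it was 0.91 and 0.78. The zones were cut at each section's own score, so they need not hold the same part of the lobule in each section. In fasted chow the markers of the 2 sides were barely opposed (mean correlation -0.06 against -0.41, -0.46 and -0.51). Unequal sampling of the lobule was thus not decided by these values. Collection at another hour cannot be told apart from feeding here: the 12 clock genes had a median absolute ratio of 0.962 in chow and 1.47 in high-fat diet, a statistic that was altered after a first version was seen, and no label gives the hour. In high-fat diet the cholesterol median was 0.48 (percentile 99.99), on the other side of 0 from chow. A feeding response of these genes that differs with diet may also underlie the pattern, but with 1 section per group the difference between animals stays open.

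Fasn was on the portal side in chow and on the central side in high-fat liver. With zones from spots of at least 3000 UMIs the difference was -1.27, and without the fasted chow section -1.29, which argues against the shallow spots of that section and against that section alone as the source. A diet effect on where fatty acid synthase is expressed is a candidate explanation found and tested on the same data. A difference between animals or slides stays open, since no label gives the slide.

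Spots high in both pathways were most frequent in fasted chow liver. Without Scd1 the share there was 8.44%, the lowest of the 4 sections. With genes weighted equally it was 22.2%, below the 29.7% of fasted high-fat liver. The pattern thus depended on the weight of Scd1 in the lipogenic score. Against refed chow it also needs the gluconeogenic score, which was high in 69.7% of fasted and 20.5% of refed chow spots. With every spot thinned to 1500 UMIs the share was 34.8%, against 17.4% in refed chow, the next highest, which argues against fewer UMIs per spot in that section as the source. The state of the tissue in its shallow spots was not tested. No biological explanation was tested for this pattern.

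For zonation, 1 of the 8 ways to turn the zone labels within sections, the real one, gave as many as 2159 genes, and the highest count of the others was 0. The zones were cut by a score from the same counts, so a turned section sets central against portal tissue. The real labels were thus bound to call the most genes, and 8 splits are also too few for a share under 0.05. No conclusion on chance is drawn from these counts.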

How the results depend on the processing

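The zones drawn from spots of at least 3000 UMIs were chosen after the data were seen; the other settings were planned. Depth limits the fasted chow section most, and with 1 section per group, leaving a section out leaves a lone section on one side. For feeding, 158 genes passed with RLE, 538 without a low-count filter and 20 with sections thinned to the smallest total, against 270; DESeq2, deeper spots and abundant genes left out gave 226, 200 and 188. With a section left out the count lay between 0 (fasted chow or fasted high-fat) and 45 (refed chow). For diet, 64 passed with RLE, 354 without the filter, 80 in deeper spots, 72 with abundant genes left out and 12 after thinning, against 131; DESeq2 gave 110, and with a section left out the count lay between 0 (refed chow, fasted chow or refed high-fat) and 18 (fasted high-fat). For zonation, DESeq2 gave 1179 and the fit without a section block 176, against 2159; RLE, no filter, 3 and 2 equal groups, 6 markers and deeper spots gave 2216, 2508, 2149, 2031, 2122 and 2193, and with a section left out 1706 (refed chow), 1816 (fasted chow), 1640.0 (refed high-fat) and 1444 (fasted high-fat) passed. The fit for feeding and diet already compares sections within the other factor, and no label gives a further pairing. The fasted mouse sections were registered apart from the refed ones, and no label says whether they were also handled apart. A difference in handling could not be told apart from feeding. For zone by feeding, 19 genes passed without the filter, 1 with DESeq2 and 4 with zones from deeper spots, against 0 in edgeR (419 at an unadjusted p under 0.05), and between 7 (refed chow) and 19 (refed high-fat) with a section left out. For zone by diet, 174 passed without the filter, 16 with DESeq2 and 18 with zones from deeper spots, against 30, and between 76 (refed chow) and 164 (fasted high-fat) with a section left out. Apart from fewer genes tested or fewer sections, the cause was not tested.

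Among list medians, gluconeogenesis moved with TMM to 0.15 in the feeding ratio of high-fat diet and to 0.19 in the diet ratio of refed liver, and with spots weighted equally to 0.0555 in refed and 0.14 in fasted liver. Lipogenesis moved to -0.35 in the feeding ratio of chow with spots weighted equally and to 0.0747 in that of high-fat diet with TMM. The share of spots high in both pathways was, in refed chow, 17.4% with thinning to 1500 UMIs, 1.76% at the 75th percentile and 20.5% with genes weighted equally; in fasted chow 34.8%, 9.27% and 22.2%, with 8.44% without Scd1 and 46.3% unthinned. In refed high-fat it was 0.882% at the 75th percentile, 19.9% with equal weights and 6.47% unthinned; in fasted high-fat 11.9% with thinning to 1500 UMIs, 1.30% at the 75th percentile, 18.7% without Scd1, 29.7% with equal weights and 12.3% unthinned. The ratio of observed to expected at the 75th percentile was 0.827 in refed chow, 0.695 in fasted chow and 0.595 in refed high-fat; without Scd1 it was 1.13 in refed chow, 0.983 in fasted chow and 1.0007 in refed high-fat, and with equal weights 1.0018 in refed high-fat, on the other side of 1. The cause was not tested.

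For the named genes and called list members, settings other than a section left out kept direction and side of the threshold in 613 values for feeding, 560 for diet, 908 for zonation, 123 for zone by feeding and 214 for zone by diet; 61, 50, 154, 0 and 4 were no longer past it and 27, 14, 19, 12 and 22 newly past it. In zonation Hbb-bs (0.0910) and Hba-a2 (0.0711), hemoglobin genes that are hard to tell apart, turned with 2 equal groups, and Fasn (0.0886) turned without a section block. With a section left out, the fits for feeding and diet do not model the other factor, so a response to that factor enters the value. The following genes turned direction; the lowest and highest fitted value is given with the section left out.

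For feeding, Pklr -0.89 (fasted high-fat) to 0.98 (refed chow) and Mup9 -1.44 (fasted chow) to 1.07 (fasted high-fat). C1qb -0.094 (fasted chow) to 0.60 (fasted high-fat) and Cidec -0.50 (fasted high-fat) to 2.68 (refed high-fat). Cd9 -0.19 (fasted chow) to 0.70 (fasted high-fat) and Cyp2b9 -8.90 (fasted high-fat) to 9.05 (refed high-fat). Aqp8 -2.78 (fasted high-fat) to 0.86 (fasted chow) and Tcim -1.80 (fasted high-fat) to 0.92 (fasted chow). Stab2 -0.0526 (fasted high-fat) to 0.31 (refed high-fat) and Dcn -0.38 (fasted high-fat) to 0.66 (refed high-fat). Ptprb -0.14 (fasted chow) to 0.31 (fasted high-fat) and G6pc -0.12 (refed chow) to 1.07 (refed high-fat). Serpina12 -1.01 (fasted high-fat) to 0.95 (refed chow) and Adgre1 -0.59 (fasted high-fat) to 0.0805 (refed high-fat). Pcx -0.0756 (fasted high-fat) to 0.36 (fasted chow) and Scd1 -0.59 (fasted chow) to 0.0888 (fasted high-fat). Vsig4 -0.0291 (refed chow) to 0.15 (refed high-fat).

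For diet, Pck1 -1.12 (refed chow) to 0.68 (fasted chow) and Elovl6 -0.78 (fasted chow) to 0.42 (refed chow). Orm2 -0.76 (refed high-fat) to 1.80 (refed chow) and Nr0b2 -0.00593 (refed chow) to 2.93 (fasted chow). Hamp -1.27 (refed high-fat) to 0.32 (refed chow) and Saa1 -2.35 (refed high-fat) to 4.48 (refed chow). Saa2 -2.55 (refed high-fat) to 5.47 (refed chow) and Me1 -1.13 (fasted high-fat) to 0.38 (refed high-fat). Vnn1 -0.39 (fasted high-fat) to 1.56 (fasted chow) and Cry1 -0.12 (refed high-fat) to 1.58 (refed chow). Hba-a1 -1.98 (fasted high-fat) to 0.0852 (refed high-fat) and Acaca -1.01 (fasted chow) to 0.48 (refed chow). Nr1d1 -3.44 (fasted high-fat) to 0.67 (fasted chow) and Acly -0.74 (fasted chow) to 0.90 (refed chow). Sox9 -1.03 (refed high-fat) to 0.00975 (fasted high-fat) and Fasn -1.34 (fasted chow) to 2.01 (refed chow). Nr1d2 -1.74 (fasted high-fat) to 0.47 (fasted chow) and Creld2 -2.68 (refed high-fat) to 0.74 (refed chow). Sdf2l1 -2.67 (refed high-fat) to 1.09 (refed chow) and Angptl4 -2.88 (fasted high-fat) to 0.39 (fasted chow).

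For zonation, Elovl6 -0.36 (refed chow) to 0.0216 (fasted high-fat) and Fasn -0.33 (refed chow) to 0.16 (fasted high-fat). Fasn stood at 0.14 without refed high-fat. For zone by feeding, Me1 -0.14 (refed high-fat) to 0.59 (refed chow) and G6pc -0.72 (fasted chow) to 0.0863 (fasted high-fat). Fasn -0.86 (refed high-fat) to 0.43 (fasted high-fat) and Pcx -0.0361 (refed chow) to 0.28 (refed high-fat). For zone by diet, Elovl6 -0.96 (refed high-fat) to 0.0186 (fasted high-fat) and Acly -0.57 (refed high-fat) to 0.23 (fasted high-fat). Ighm -2.65 (fasted high-fat) to 0.96 (refed chow) and Fbp1 -0.13 (refed high-fat) to 0.20 (fasted high-fat). Pcx -0.0751 (refed chow) to 0.27 (fasted chow) and Scd1 -0.0975 (fasted high-fat) to 0.19 (refed high-fat). The cause was not tested.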

Other observations

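The tests in this part are the planned ones. Cell type markers gave few calls for feeding and diet. Kupffer cell markers summed to 244 CPM in refed chow, 302 in fasted chow, 290.0 in refed high-fat and 257 in fasted high-fat, with medians of 0.21 and -0.08 for feeding in chow and high-fat diet and 0.39 and -0.03 for diet in refed and fasted liver, and 0 of 9 passed in edgeR for feeding or diet, over all genes or adjusted over the list alone. Recruited macrophage medians were 0.25 and 0.13 for feeding in chow and high-fat diet and -0.03 and -0.15 for diet in refed and fasted liver, of 2 measured members, and the last 3 changed sign under another scaling. Endothelial medians were 0.16 and 0.19 for feeding in chow and high-fat diet and -0.12 and -0.17 for diet in refed and fasted liver, with no gene past the threshold. Stellate cell medians were -0.05 and 0.24 for feeding in chow and high-fat diet and 0.66 and 0.74 for diet in refed and fasted liver, the first of which changed sign under another scaling; 0 of 8 passed for diet over all genes and Dcn, Reln and Colec11 when adjusted over the list alone, all higher. B and plasma cell medians were -1.56 and 0.00 for feeding in chow and high-fat diet and -1.21 and 0.35 for diet in refed and fasted liver, of 2 measured members, of which the high-fat feeding and the fasted diet values changed sign under another scaling, and Igkc and Jchain were lower in fasted liver when adjusted over the list alone. Erythroid markers (4 hemoglobin genes of a near-identical family, and Alas2) had medians of 0.37 and 1.92 for feeding in chow and high-fat diet. For diet the medians were -1.52 in refed and -0.12 in fasted liver, the last of which was 0.74 with spots weighted equally. Hba-a2 rose with fasting (edgeR, adjusted p = 0.0105), and the 4 hemoglobin genes of the 5 markers passed when adjusted over the list alone.

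Markers with few counts are given as sums of CPM in refed chow, fasted chow, refed high-fat and fasted high-fat: cholangiocyte 12.2, 13.1, 9.03 and 7.94, T and NK cell 3.02, 6.95, 2.20 and 2.38, neutrophil 4.90, 2.38, 4.53 and 2.45, smooth muscle 6.17, 11.3, 4.53 and 5.45, and mesothelium 2.95, 4.31, 4.85 and 1.49. The medians of amino acid genes were -0.17 and -0.47 for feeding in chow and high-fat diet and 0.33 and -0.03 for diet in refed and fasted liver, the first of which was 0.10 with spots weighted equally. Those of interferon genes were 0.16 and 0.46 for feeding in chow and high-fat diet and -0.10 and 0.26 for diet in refed and fasted liver, the first of which was -0.01 with spots weighted equally, and those of stress genes 0.33 and -0.42 for feeding in chow and high-fat diet and -0.20 and -0.42 for diet in refed and fasted liver. Fibrosis medians were 0.68 and 0.92 for feeding in chow and high-fat diet and 0.47 and 0.45 for diet in refed and fasted liver, those of bile acid genes -0.09 and -0.08 for feeding in chow and high-fat diet and 0.16 and 0.23 for diet in refed and fasted liver and those of clock genes 0.18 and 0.80 for feeding in chow and high-fat diet and -0.60 and -0.26 for diet in refed and fasted liver. Lipid droplet medians for feeding were 0.17 in chow, -0.08 with spots weighted equally, and 0.93 in high-fat diet. The central score list had medians of 0.58 and 0.26 for feeding in chow and high-fat diet and 0.13 and -0.05 for diet in refed and fasted liver, of which both diet values changed sign under another scaling, and the portal score list 0.12 and -0.46 for feeding in chow and high-fat diet and 0.31 and -0.03 for diet in refed and fasted liver, of which the last changed sign. The core lists had medians of 0.50 and 0.27 for feeding in chow and high-fat diet and 0.28 and 0.21 for diet in refed and fasted liver for gluconeogenesis and -1.32 and -0.10 for feeding in chow and high-fat diet and -0.96 and 0.45 for diet in refed and fasted liver for lipogenesis. The diet medians of fat oxidation were -0.03 refed, 0.06 with TMM, and -0.11 fasted. The deposited Moran score of Fasn was 0.114 in refed chow, 0.0162 in fasted chow, 0.271 in refed high-fat and 0.184 in fasted high-fat; that of Pck1 was 0.124, 0.196, 0.268 and 0.241 and that of Scd1 0.243, 0.163, 0.446 and 0.352. In the humanized section SDS had the highest score, 0.471.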
